A study of Homo sapiens with 6 samples.

How the data were processed

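RNA recovered by precipitation with an antibody against the myc tag was sequenced from transfected HEK cells in 6 libraries, 3 named wild-type control and 3 named AAA mutant. Per the labels' protocols, the cells were transfected with calcium phosphate, ribosomal RNA was depleted after the precipitation, and libraries were made with a commercial RNA-seq kit. Group and replicate number came from the sample titles. The labels do not state that replicates of a group came from separate cultures, so p-values measure the spread between these libraries, which may in part be technical. Libraries of input RNA were not analysed here.

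The deposited table holds raw counts per gene, whole numbers that were not normalized, for 60671 Ensembl gene IDs in 6 columns, all of which were used. Per the submitters' processing notes, STAR 2.7.6a, FastQC and featureCounts were used before deposit. The genome build, the annotation release and the strand and overlap settings of the counting are not given in the sources used here. Symbols were taken from a table of gene IDs, which held 60647 of the IDs. Positions, spans, exon lengths and GC content came from GENCODE release 29 on GRCh38, which held 58453 of the IDs, so coordinates below are those of that reference and not of the submitters' files. No row lacked a gene ID.

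The counts behaved as sums over whole gene bodies. CNTNAP2, a neuronal gene with a span of 2305 kb and 16.7 kb of exons, had 15318 counts in wild-type control replicate 2. At the count density of the olfactory receptor genes of that library, 10985 counts were predicted for the whole span and 79.4 for the exons. CNTNAP2 was chosen for this check after the counts were seen. Overlapping genes could each receive the same read: of the 18051 IDs with at least 1000 counts in total, 12 shared all 6 counts with another ID. Values of overlapping and antisense genes are therefore uncertain.

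Background was measured as the count density, in counts per base of gene span, over 404 olfactory receptor genes, a family of sensory receptors taken here as little transcribed. The background share of a library is that density times the summed span of all nuclear genes, divided by their summed count. Its intervals are 95% exact Poisson intervals of the olfactory receptor counts and cover counting error only. Genes whose average count lay more than 8 times above background, on the log scale over the 6 libraries, are called genes far above background; 4425 tested genes met this.

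Genes were tested with edgeR 4.0.16 under R 4.3.3: filterByExpr with default settings, TMM factors, and the quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 33375 genes. The fit had no replicate block, as fixed before the data were examined. The standard error of a log2 fold change is its size divided by the square root of F. Log2 CPM used a prior count of 1. Because the groups share replicate numbers, the same fit with the replicate number as a block had been set as an alternative. The numbers were then checked for pairing by correlating, across genes, each library's deviation from its group mean. Libraries with the same number gave r = 0.41, 0.76 and 0.90 for numbers 1, 2 and 3, and each library correlated best with its own number. The pairing comes from this check, since the labels do not say that a number marks a shared day or batch, and blocked values are printed beside results whose call they change. A pair difference is the log2 CPM of the mutant library minus that of the control library with the same number.

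A set of 34 gene lists was fixed before the data were examined, and 33 had at least 5 tested members. They were tested with camera in limma 3.58.1 with the preset correlation of 0.01, with camera and an estimated correlation, and with fry, which tests whether the genes of a list move one way on balance. Shares of counts per RNA class were compared by an exact two-sided permutation test, for which 3 libraries against 3 cannot give a p below 0.10. The genes named were fixed by rule. SYNJ2BP, COX16, the SYNJ2BP-COX16 readthrough gene, SYNJ2 and PINK1 were always named. Up to 12 genes per direction were named among called genes with a symbol, an average log2 CPM of at least 2 and the same direction in every replicate or pair, by size of change. Where the fit without the block called none, the 5 genes with the smallest p per direction were named as values only. Each list gave up to 4 called members by smallest p, or up to 2 as values only. The value of 1 gene taken by this rule is not reported here. In the text, the rule for called genes was applied to the blocked fit.

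The test was run on simulated counts for the 33375 genes with the means, library sizes and replicate effects of this comparison. Without the block it recovered 0% of 50 genes changed at each of 1.5, 2, 4 and 8-fold. With the block it recovered 2% at 1.5-fold, 36% at 2-fold and 100% at 4-fold and 8-fold, with 5 false calls among the unchanged genes. The simulated means were shared within a pair except for the changed genes, so differences in background within a pair were not simulated. These false calls therefore do not measure error from such differences. Alternatives covered the normalization, the test (DESeq2 1.42.0, limma-voom, robust edgeR), the filter, the threshold, the genes counted and each replicate left out. Added after the data were seen were the other settings of the blocked fit, among them scaling factors from genes far above background, subtraction of the background, and removal of trends over gene span and GC content. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.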

Results

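RNA bound to a myc-tagged protein was precipitated from HEK cells, a line derived from human embryonic kidney, and counted per gene in 6 libraries. The labels name SYNJ2BP, an outer mitochondrial membrane protein that binds the lipid phosphatase SYNJ2, as the protein whose RNA was collected. They give 3 replicates of a wild-type control and 3 of a SYNJ2BP AAA mutant. Which residues the mutant name refers to, and what the control cells express, is not given in the sources used here. The names of the mutant libraries carry the term mito (AAA.mito) and those of the control do not (WT.Control). The meaning of this term is not given either, so the groups may differ in more than the mutation. The series concerns the transport of the mRNA of PINK1, a kinase that marks damaged mitochondria for removal, on neuronal mitochondria through SYNJ2. The comparison asked which RNAs were recovered to a different extent with the mutant.

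Total counts in the control libraries were 15010016, 11067938 and 61912640 for replicates 1, 2 and 3. In the mutant libraries they were 7347998, 3287218 and 73331652. Olfactory receptor genes, which serve here as a measure of background, set the libraries apart by replicate number more than by group. The background share of nuclear gene counts was 37.9% (95% interval 37.1 to 38.8), 84.2% (82.7 to 85.7) and 7.44% (7.25 to 7.63) in control replicates 1, 2 and 3. It was 55.3% (53.8 to 56.8), 81.8% (79.0 to 84.6) and 6.56% (6.40 to 6.72) in mutant replicates 1, 2 and 3. Counts above background were thus most plentiful in both replicate 3 libraries and scarcest in both replicate 2 libraries. The first principal component of log2 CPM held 72.8% of the variance and placed both replicate 3 libraries at one end and both replicate 2 libraries at the other.

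**Figure D1:**
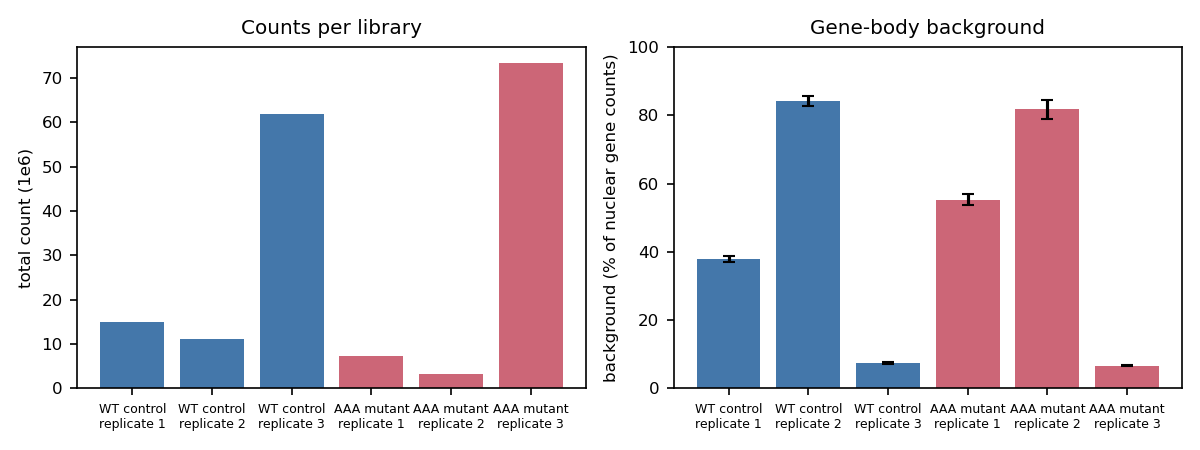
The left panel plots the total count of each library (1e6 counts), and the right panel the estimated gene-body background as a percent of nuclear gene counts, with 95% Poisson intervals. Bars are blue for wild-type control and red for AAA mutant; background ranged from 6.56% in mutant replicate 3 to 84.2% in control replicate 2.

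With libraries of the same number treated as pairs, 467 genes fell and 2 rose in the mutant. MOAP1, an apoptosis modulator, fell most among the genes named by rule, with a log2 fold change of −2.93 ± 0.34 (SE, n = 3 pairs; adjusted p = 4.4e-06). RTL6, derived from a retrotransposon, fell by 2.61 ± 0.31 and MTA2, a subunit of a chromatin-remodelling deacetylase complex, by 2.39 ± 0.34. MFN2, the GTPase that fuses outer mitochondrial membranes, fell by 2.28 ± 0.39 (adjusted p = 0.000701), and ESYT1, a tether between the endoplasmic reticulum and the plasma membrane, by 2.34 ± 0.41. Without the pairs no gene passed the test, so these falls rest on the pairing. They rest on other choices too: the count fell to 8 with scaling factors from genes far above background. It fell to 0 without pair 3 and to 0 with background subtracted.

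MFN2 (ENSG00000116688, chromosome 1, 11980181 to 12013514) had 321 ± 250 CPM in the control and 49.4 ± 29.3 CPM in the mutant libraries (SD, n = 3). Its pair differences were −3.16, −0.82 and −2.69 in pairs 1, 2 and 3. MOAP1 (ENSG00000165943, chromosome 14, 93182196 to 93184928) had 101 ± 96.3 CPM against 10.7 ± 8.57 CPM, and pair differences of −3.35, −1.04 and −3.32. Other genes that fell by the naming rule were TATDN2 (−2.46), SRXN1, which restores oxidized peroxiredoxins (−2.42), UNC119B, a carrier of lipid-modified proteins (−2.26), and NOP2, an rRNA methyltransferase (−2.22). The list ended with MBD1, a reader of methylated DNA (−2.20), the noncoding SNRPA1-DT (−2.15) and CPT1B, which loads fatty acids for import into mitochondria (−2.15). SRXN1, ESYT1, TATDN2, UNC119B, NOP2, SNRPA1-DT and CPT1B overlap other annotated genes, so part of their counts could belong to those. All 12 genes were lower in the mutant in 3 of 3 pairs, as the naming rule requires. SRXN1, MBD1, SNRPA1-DT and CPT1B lay near background in replicate 2, at 1.68, 1.69, 1.59 and 1.25 times background in the control and 1.44, 0.603, 1.01 and 0.467 times in the mutant, so their pair 2 values came from such counts.

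Of the 467 genes that fell, 367 were annotated as protein-coding and 75 as antisense, and 434 were lower in all 3 pairs. Their median pair differences were −1.72, −0.82 and −1.23. The 3072 protein-coding genes far above background had medians of −0.89, −0.01 and −0.68, so with TMM factors many transcripts outside the called set were also lower in pairs 1 and 3. The median of all genes far above background in the blocked fit was −0.50 with TMM factors and 0.030 with factors taken from these genes themselves. The median over all tested genes was −0.08 in the blocked fit. Both rises were copies of SNORD3D, a small nucleolar RNA, under 2 IDs whose positions overlap (1.95 ± 0.49, adjusted p = 0.0315). Their pair differences were 5.33, −2.02 and 1.58, so the direction was not shared by all pairs, and the naming rule took no gene that rose.

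**Figure D2:**
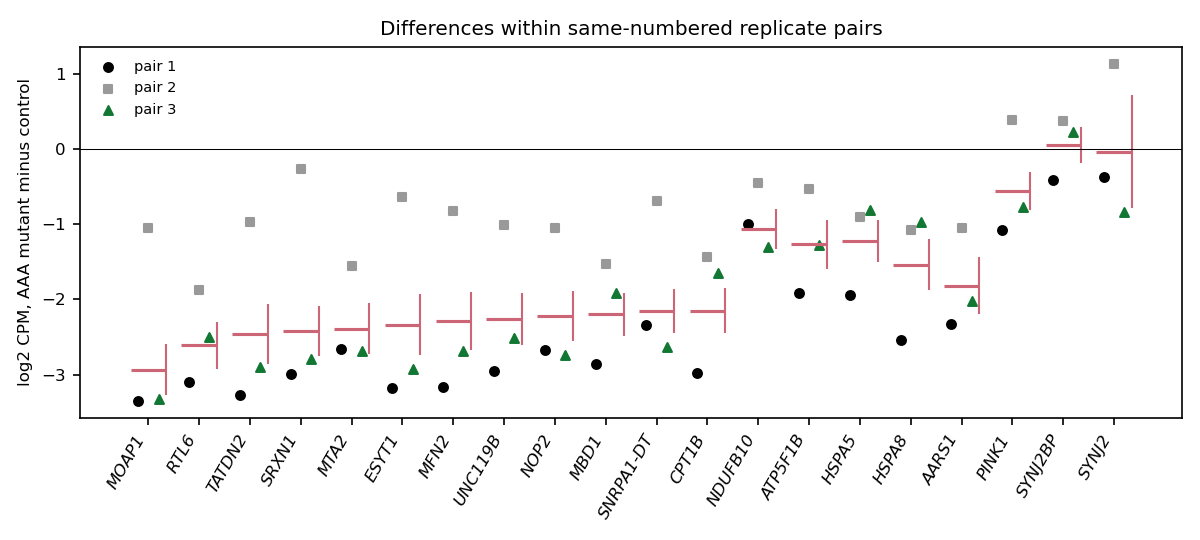
Log2 CPM of the AAA mutant library minus the control library of the same number, for pairs 1 (circles), 2 (squares) and 3 (triangles); horizontal bars are blocked log2 fold changes and vertical bars their standard errors. MOAP1 and the 11 genes to its right lie below 0 in all pairs, while PINK1, SYNJ2BP and SYNJ2 have pairs on both sides of 0.

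Without the block, edgeR called 0 of 33375 genes, with 25 at an unadjusted p under 0.05, 23 of them lower in the mutant. DESeq2 and limma-voom also called 0, with 70 and 2 genes at that unadjusted level. By the naming rule, the smallest p-values among genes lower in the mutant belonged to MOAP1 (−3.22 ± 1.19), MFN2 (−2.70 ± 1.00), ESYT1 (−2.86 ± 1.08), NRIP3 (−1.98 ± 0.75) and NOP2 (−2.58 ± 1.00). Among genes higher in the mutant they belonged to ASB17 (1.35 ± 0.86), LURAP1L (0.85 ± 0.60), VWA7 (1.26 ± 0.89), PROKR1 (1.46 ± 1.04) and IGSF6 (0.97 ± 0.69). None of the 10 passed adjustment. The biological coefficient of variation was 0.746 without the block and 0.249 with it.

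The count of 469 with the block was 0 without pair 3, 37 without pair 1 and 259 without pair 2, where 463, 467 and 467 of the genes that fell were tested and had medians of −1.30 (median SE 0.38), −1.09 (0.38) and −1.27 (0.37). With all 3 pairs, on which these genes were chosen, the median was −1.27 (0.28). The count was 8 with scaling factors taken from genes far above background, where all 467 genes that fell had a median of −0.74 (median SE 0.38).

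PINK1 (ENSG00000158828, chromosome 1, 20633455 to 20651511) had 34.5 ± 22.5 CPM in the control and 20.5 ± 8.59 CPM in the mutant libraries (SD, n = 3). Its log2 fold change was −0.74 ± 0.77, and −0.56 ± 0.26 with the block (adjusted p = 0.439). The pairs differed in direction, at −1.07, 0.39 and −0.77. PINK1 counts lay 12.6, 1.46 and 47.2 times above background in control replicates 1, 2 and 3, and 5.40, 1.99 and 32.9 times in the mutant, so its pair 2 value came from counts near background. The unadjusted p of PINK1 in the quasi-likelihood F test was 0.359 without the block and 0.0381 with it. After adjustment over all tested genes, a difference in PINK1 recovery was not detected at this spread. PINK1 overlaps the antisense gene PINK1-AS, and the scaling from genes far above background moved its blocked value to −0.03.

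SYNJ2 RNA was among the most abundant protein-coding RNAs in every library. SYNJ2 (ENSG00000078269, chromosome 6, 157981887 to 158099176) had 4035 ± 2016 CPM in the control and 3980 ± 1736 CPM in the mutant (SD, n = 3). It ranked between 1 and 5 among 19890 protein-coding genes by count. Its log2 fold change was −0.02 ± 0.92, and −0.03 ± 0.76 with the block, with pair differences of −0.36, 1.14 and −0.83, and its sign changed with the scaling. SYNJ2BP (ENSG00000213463, chromosome 14, 70366496 to 70417061) had 36.9 ± 28.0 CPM in the control and 39.7 ± 34.6 CPM in the mutant. The log2 fold change of SYNJ2BP was 0.11 ± 0.83, and 0.06 ± 0.24 with the block (adjusted p = 0.988). SYNJ2BP counts were 2.71, 0.855 and 24.2 times background in the control and 1.83, 1.15 and 33.6 times in the mutant. COX16, an assembly factor of cytochrome c oxidase encoded next to SYNJ2BP, had a log2 fold change of −0.11 ± 0.80. The readthrough gene SYNJ2BP-COX16, whose position overlaps both, had −0.10 ± 0.80. Its counts nearly equalled those of COX16 in each library, at 629 against 635 in control replicate 1, where SYNJ2BP had 399. Whether reads of SYNJ2BP were also counted for the readthrough gene cannot be told, since the gene models used for the counting are not given. None of the 3 passed the test with or without the block.

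**Figure D3:**
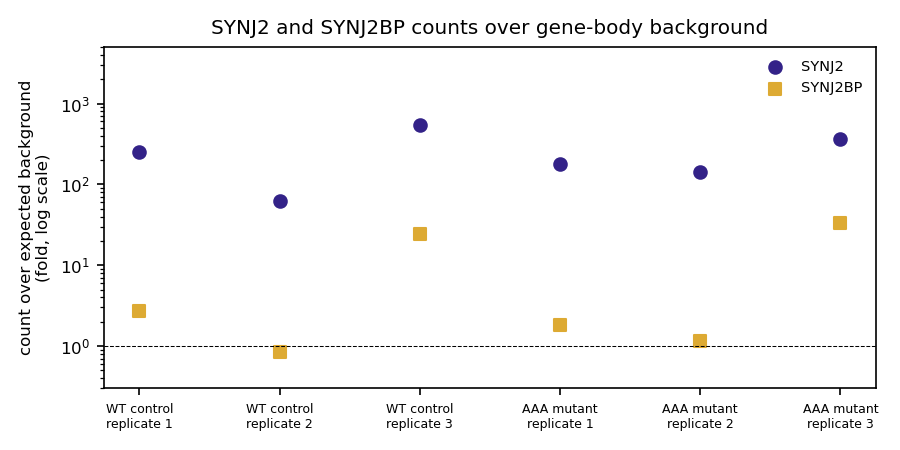
Counts of SYNJ2 (circles) and SYNJ2BP (squares) divided by the count predicted from gene-body background, per library, on a log axis; the dashed line marks background. SYNJ2 lies between 61.9 and 541 times background, and SYNJ2BP between 0.855 and 33.6 times.

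Among genes for mitochondrial proteins, members of several lists fell in the blocked fit. For comparison, 369 of the 4425 genes far above background fell, and 467 of all 33375 tested genes. Far above background were 50 of the 79 subunits below, 39 of 78 mitochondrial and 80 of 80 cytosolic ribosomal proteins. Counts of called members were not tested against these shares and do not by themselves set a list apart. Of 79 nuclear-encoded subunits of oxidative phosphorylation, 6 fell and 73 did not pass, with 21 passing when adjusted over the list alone. Among the 6 were NDUFB10 (−1.06 ± 0.27) and NDUFA6 (−1.04 ± 0.28) of complex I, and ATP5F1B (−1.27 ± 0.33) and ATP5MC1 (−1.15 ± 0.30) of ATP synthase. ATP5MC1 was higher in the mutant in pair 2, by 0.36. Of 78 mitochondrial ribosomal proteins, 6 fell, MRPS26 (−1.10), MRPS2 (−0.98), MRPL11 (−0.93) and MRPL10 (−0.98) among them, and 12 passed when adjusted over the list alone. Of 36 protein import genes, TOMM40L (−1.95 ± 0.28), GFER (−1.67 ± 0.28) and PMPCA (−1.30 ± 0.27) fell, and 8 passed when adjusted over the list alone. Of 35 mitophagy genes, MFN2 and the ubiquitin ligase MUL1 (−1.14 ± 0.27) fell, and 6 passed when adjusted over the list alone. MIEF1, a receptor for the fission GTPase DRP1, fell by 1.08 ± 0.26 and was, with MFN2, the called part of 30 dynamics and transport genes, of which 3 passed when adjusted over the list alone. Of 50 mitochondrial carriers, the citrate carrier SLC25A1 (−1.19) and the ADP/ATP carrier SLC25A5 (−1.14) fell, and 4 passed when adjusted over the list alone. VARS2 (−1.17) was the called gene among 28 mitochondrial tRNA synthetases and translation factors, of which 4 passed when adjusted over the list alone. With upper quartile factors, 0 of the subunits of oxidative phosphorylation, 0 of the mitochondrial ribosomal proteins and 3 of the import genes were called lower, and with scaling from genes far above background no member of any list was.

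No gene passed among 22 genes of the TCA cycle or 20 mitochondrial chaperones and proteases, although 8 and 7 passed when adjusted over the list alone. The smallest blocked p-values there were those of SDHA (−1.01) and IDH3B (−0.76), and of STOML2 (−0.88) and HSPA9 (−1.05). Of 21 partners of SYNJ2BP and SYNJ2 and mRNA tethers, none passed, and 1 did when adjusted over the list alone. RRBP1, the ribosome-binding partner of SYNJ2BP, had −1.05 ± 0.30 (adjusted p = 0.0714), and CLUH, which binds mRNAs for mitochondrial proteins, had −0.89 ± 0.31 (adjusted p = 0.167). The 13 mRNAs encoded in mitochondrial DNA had a median of 0.20, with pair medians of 0.37, 0.95 and −0.79, and none passed in either adjustment. MT-ND3 (0.34) and MT-ND2 (0.41) had the smallest p-values of that list.

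Stress and housekeeping lists held called genes too, to be read against the same shares. Of 20 heat shock genes, the chaperones HSPA8 (−1.54 ± 0.34) and HSPH1 (−1.11), their cochaperone STIP1 (−1.26) and the collagen chaperone SERPINH1 (−1.04) fell, and 12 passed when adjusted over the list alone. Of 32 genes of the integrated stress response, AARS1 (−1.82 ± 0.38), PPP1R15A (−1.26), ASNS (−1.18) and DDIT4 (−1.02) fell, and 8 passed when adjusted over the list alone. HYOU1 (−1.80) and HSPA5 (−1.23), chaperones of the endoplasmic reticulum, fell among 25 ER stress genes, and 10 passed when adjusted over the list alone. SRPRA (−1.27), a subunit of the signal recognition particle receptor, fell among 33 secretory entry genes, and 9 passed when adjusted over the list alone. RPS26 (−1.56) and RPL36AL (−1.11) fell among 80 cytosolic ribosomal proteins, and 4 passed when adjusted over the list alone. CDC20 (−1.42) and PLK1 (−1.20), mitotic regulators, fell among 28 G2/M genes, and 14 passed when adjusted over the list alone. TUBB4B (−1.13) was the called gene of 26 cytoskeletal genes, with 15 passing when adjusted over the list alone. With upper quartile factors, 2 heat shock genes, 3 of the integrated stress response, 2 of ER stress and 0 of the cytoskeleton were called lower.

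As lists, 13 of 33 were called lower by camera with the preset correlation and no block, and 18 with the block. Camera sets a list against all other tested genes. In the blocked fit the median was −0.08 over all tested genes and −0.50 over genes far above background. Oxidative phosphorylation (−0.45), the TCA cycle (−0.48) and cytosolic ribosomal proteins (−0.53) lay near the latter, heat shock (−0.86) and the cytoskeleton (−0.74) below it. A call thus does not set a list apart from other genes far above background. The 13 were oxidative phosphorylation, mitochondrial and cytosolic ribosomal proteins, import, TCA cycle, mitochondrial chaperones, secretory entry, ER stress, the integrated stress response, heat shock, immediate early genes, G2/M and the cytoskeleton. None was called with an estimated correlation (adjusted p = 0.915 without the block and 0.753 with it, for each of the 13). With fry none was called either, and the adjusted p was 0.995 without the block for each of these lists. In the fit without the block, where leaving out 1 library leaves its pair incomplete, 15 lists were called and all were higher without control replicate 3, and 9 were called and all were higher without mutant replicate 2. With the block and a whole pair left out, 8 lists were called lower without pair 1, 19 without pair 2 and 15 without pair 3, where 2 were called higher. Scaling from genes far above background shifted the median of all genes to 0.40, from −0.08, and the list medians with it, so that 9 of 34 lay below 0, against 32 before. Relative to the median of all genes, 28 of 34 lay lower with that scaling, against 29 before. New factors shift most genes by a similar amount, so this likeness was largely fixed in advance and does not test the lists.

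The share of counts in each RNA class differed between the groups by less than the larger within-group SD. The permutation test did not use the pairs. Mitochondrially encoded mRNA made up 2.14% ± 1.28 of the control and 3.18% ± 2.43 of the mutant libraries (SD, n = 3; exact permutation p = 0.6). Ribosomal RNA held 2.95% ± 3.22 against 1.53% ± 0.876 (exact permutation p = 0.7), and its mitochondrial members MT-RNR1 and MT-RNR2 had blocked log2 fold changes of −0.60 and −0.55 that did not pass. Small structural RNA held 2.15% ± 2.00 against 1.94% ± 1.20 (exact permutation p = 1), and histone genes 0.311% ± 0.370 against 0.157% ± 0.160 (exact permutation p = 0.7). SYNJ2 held 0.376% ± 0.180 against 0.466% ± 0.281, and SYNJ2BP 0.00303% ± 0.00139 against 0.00360% ± 0.00195 (exact permutation p = 0.7 for each). The 10 most abundant genes of each library held 7.87% ± 4.93 against 6.51% ± 1.29 (exact permutation p = 0.8). The smallest p these 7 comparisons could reach was 0.1, and the adjusted p was at least 0.933 for each.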

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

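The blocked settings other than the block itself, and the fits without both replicate 2 libraries, were added after the data were seen. Without the block every setting called 0 genes, with 2 to 627 genes at an unadjusted p under 0.05. The replicate block called 469, and it changed no call of PINK1, SYNJ2 or SYNJ2BP. With the block, the count was 576 with median-of-ratios factors, 524 with DESeq2 and 637 with the robust fit. It was 312 with upper quartile factors, 288 with library totals, 1492 with limma-voom, 231 without a filter and 279 with the stricter filter. It fell to 89 with the span trend removed, 56 with span and GC trends removed, 8 with factors from genes far above background, and 0 with background subtracted. Leaving out a pair gave 0 to 259. The genes that fell, 463 to 467 of which were tested, then had medians of −1.30 to −1.09 (median SE 0.37 to 0.38), and 464 of them −1.41 (0.55) with background subtracted, against −1.27 (0.28) in the fit they were chosen on, so the error was larger where these calls ended. Each of these fits reuses pairs on which the genes were chosen, so the kept medians are not independent evidence. In pairs 1 and 3 alone, background subtraction gave 0 and factors from genes far above background gave 6120, of which 5920 were higher in the mutant. MFN2 kept a blocked value between −2.76 and −1.78 in all these settings, but lost its call without pair 1 (adjusted p = 0.353), without pair 3 (0.353), with factors from genes far above background (0.0986) and with background subtracted (0.994). None of the 61 called genes named by rule turned its direction in any blocked setting except RNY3, at 0.082 without pair 3 and −2.15 without pair 1, but all 61 lost their call with background subtracted, as did 56 with factors from genes far above background, 41 with span and GC trends removed and all 59 that were tested without pair 3. SYNJ2, at −0.02, changed sign in many settings. Without the block it was 0.06 with median-of-ratios factors and with DESeq2 (both 0.064), 0.29 with upper quartile factors, 0.31 with totals, 0.077 with the stricter filter and 0.066 with structural and mitochondrial RNA left out. With the block it was 0.0086 and 0.0087 with median-of-ratios factors and DESeq2, 0.13 with upper quartile factors, totals and limma-voom (0.131, 0.132 and 0.126), 0.45 with factors from genes far above background (0.14 in pairs 1 and 3), 0.043 without a filter, 0.091 with the stricter filter and 0.12 with background subtracted. Leaving out libraries gave −0.43 to 0.41 for SYNJ2 and −0.87 to 1.11 for SYNJ2BP. PINK1 stayed below 0 and uncalled in all settings. The 13 lists became 18 with the block, 7 with limma-voom and 0 without a filter. They became 0 with an estimated correlation or fry, with or without the block, 4 to 29 with 1 library left out, and 8, 19 and 17 with the block and without pair 1, 2 or 3. The cause was not tested, except where fewer libraries or factors from other genes define the setting. No share of an RNA class moved by more than its larger within-group SD, and since every row names a gene, the planned shares with unnamed rows give the same values. Depth limits the pair 2 values, since mutant replicate 2 had 3287218 counts and background made up over 80% of nuclear counts in both replicate 2 libraries.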

Other observations

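Tests chosen only after the data were seen were those of the second silent gene set, of scaling, of gene span, of the transfer between pairs and of SYNJ2 against SYNJ2BP. Beyond the lists described above, a few others held called genes in the blocked fit, none of which was called with factors from genes far above background. Of 540 ZNF zinc finger genes, 11 fell, with ZNF768 (−1.91), ZNF740 (−1.83), ZNF778 (−1.66) and ZNF16 (−1.55) leading by p, and 11 passed when adjusted over the list alone. Of 48 replication-dependent histone genes, 5 fell, H2AC25 (−1.27), H3C7 (−1.53), H2BC26 (−1.10) and H2BC21 (−1.34) among them, and 13 passed when adjusted over the list alone. H2BC21 was higher in the mutant in pair 2, by 0.89. Among 165 small RNA genes, RNY3, the Y3 RNA (−1.95), and RNU11, an RNA of the minor spliceosome (−1.37), fell while the copies of SNORD3D rose. RNY3 had pair differences of −0.80, 1.14 and −2.90. FXR2, a relative of the fragile X protein, fell by 1.32 among 36 RNA-binding proteins of mRNA transport, and AP2M1, a clathrin adaptor subunit, by 1.00 among 34 endocytosis genes.

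Markers of other cell types were included among the lists. None of 21 neuronal or 13 blood cell genes passed, and the values with the smallest p were NEFL (−0.73), INA (−0.70), LYZ (1.77) and CORO1A (−1.06). TAGLN (−1.56) fell among 16 fibroblast genes and KRT18 (−1.21) among 14 epithelial genes. No gene passed among 30 interferon genes (STAT2 −0.72, IFIT5 −0.91), 32 immediate early genes (SRF −0.69, IER2 −0.69), 28 genes of glycolysis (PGAM1 −0.96, TPI1 −0.90) or 25 of cholesterol synthesis (EBP −1.03). The same held for 23 p53 targets (AEN −1.18, SESN2 −1.30) and 27 nuclear retained RNAs (SRSF5 −0.67, DDX39B −0.69). Adjusted over the list alone, 3 p53 targets, 2 cholesterol genes and 1 glycolysis gene passed, and no interferon, immediate early or nuclear retained gene did.

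The count density over olfactory receptor genes differed between libraries, and a candidate explanation is background spread evenly over the genome, such as DNA carried through the precipitation. A second silent set of keratin-associated protein, defensin, taste and vomeronasal receptor genes was used as a check. In genes that overlap no other gene (281 and 132), the density of the second set was 0.769 and 0.748 times that of the olfactory receptor set in control replicates 1 and 2. It was 0.846 and 0.748 times in mutant replicates 1 and 2. A fully even background predicts a ratio of 1 in each library, so the background shares are approximate. Between these 4 libraries the ratio was steady, as an even background also predicts: the log2 ratio of the highest to the lowest was 0.18. Over all 6 libraries it was 0.82, which leaves replicate 3 open. With overlapping genes kept it was 4.52, mostly from TAS2R14, a taste receptor gene named after its value was seen, which held 34171 of the 39162 counts of the second set in mutant replicate 3.

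Nearly all genes called with the block were lower in the mutant. With the trend over gene span removed, the median of those genes was −1.10 (median SE 0.26), against −1.27 (median SE 0.28) before. Because the genes were chosen for low values in these same data, that median could be expected to stay below 0 in any case. It therefore does not decide whether span was the whole cause. All 89 calls of that fit were lower, so a smooth trend over span did not account for these. Of 465 genes, 87 stayed called. Over all 465 the median fold was slightly smaller and the error no larger, so a contribution of span stays open. Scaling could account for the common direction: with factors from genes far above background, 8 of the 467 genes stayed called. The median of all 467 was then −0.74 (median SE 0.38), so calls ended through a smaller fold and a larger error. The median of all tested genes moved from −0.08 to 0.40. A part specific to particular mRNAs remains as a hypothesis: after span and GC trends were removed in 3072 protein-coding genes far above background, the 307 lowest of a pair were lower than the other genes in another pair in 5 of 6 transfers (−0.36 from pair 1 to pair 3, range −0.66 to −0.19), which 0 of 10000 random sets reached, and lay at −0.01 from pair 2 to pair 3, which 3210 sets reached, while the 307 highest were likewise higher in 4 of 6 (0.16 to 0.21, 0 of 10000), so the carry-over ran both ways. The random sets treat genes as independent, and differences in expression level were not removed. These counts therefore cannot tell a difference of particular mRNAs from one that groups of genes share. MOAP1, RTL6, MBD1, SRXN1 and MTA2 were the genes with a symbol that kept their call under the factors from genes far above background, and may be candidates for RNAs recovered less with the mutant, although these 5 had 12 to 26 counts in mutant replicate 2, where MBD1, SRXN1 and RTL6 lay under 2 times background, and no gene was called without pair 3, where the error was larger. No gene was called with background subtracted either. Without input libraries, lower recovery cannot be told from lower abundance in the cells.

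The splits are too few for a share under 0.05. Without the block, the real split of the 6 libraries gave 0 genes, so all 10 splits gave as many, and the highest other gave 5413. That split set control replicates 1 and 3 and mutant replicate 3 against the rest, which points to the background structure of the libraries. With the block, 1 of the 4 splits that part all pairs, the real one, gave 469 genes, and the highest other gave 46.

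SYNJ2 counts exceeded SYNJ2BP counts by 24.9 to 283 times, although the labels name SYNJ2BP. A construct carrying human SYNJ2BP sequence could raise SYNJ2BP in every library, but SYNJ2BP lay under 3 times background in 4 of the 6 libraries. This does not decide against such a construct, since a precipitate need not hold the construct's own RNA. Background was also taken over the whole gene span, of which a construct may carry a small part. A candidate explanation is a construct carrying SYNJ2 sequence: SYNJ2 lay at least 61.9 times above background in all 6 libraries and ranked 1 to 5 among 19890 protein-coding genes, also where most transcripts were near background. A construct of SYNJ2BP from another species or with altered codons, and SYNJ2 mRNA bound by the precipitated protein, stay open and were not tested. Because SYNJ2 was as abundant in control as in mutant libraries within their spread, its level does not tell the groups apart.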
